A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

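Transcript levels of budding yeast were measured on 9 Affymetrix Yeast Genome 2.0 arrays, 1 per culture sample, hybridised with biotinylated cRNA made from 100 ng of total RNA. The deposited value table held log2 expression values for 5716 probe sets, made with RMA (robust multi-array average, which corrects background, normalizes quantiles and summarizes probes) and Transcriptome Analysis Console 2.0, both named per the submitters' processing notes. Further settings of these steps were not given in the sources used here. Each deposited array column had nearly the same distribution, with medians over the tested probe sets between 6.86 and 6.94, so a change shared by all transcripts of a culture would not appear in these values. RMA values compress the changes of dim probe sets, and array number rather than read depth limits the precision. A separate deposited table gave the authors' own comparisons as signed linear fold changes and p-values. The authors' fold changes were recomputed from the deposited log2 values as a check of sign and scale, and their p-values were compared with Tukey's honest significant difference on the same values. No scan dates or hybridisation batches were given in the sources used here, so batches were not tested.

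Samples were placed in groups by their descriptions. NR denoted growth in rich medium (YPD) with 2% glucose, CR growth in the same medium with 0.5% glucose, and RM growth with 2% glucose and 100 nM rapamycin, an inhibitor of the TORC1 kinase complex. All cultures were grown at 30 °C and harvested at day 5, with 3 arrays per group described as biological replicates. Probe sets were named through the platform annotation, with symbols brought up to date through the RefSeq gene table of assembly R64. Of the 5716 probe sets, 5498 were paired with 1 gene and tested, 0 were paired with several, and 218 were unpaired and left out of the tests. The tested probe sets represented 5449 different genes, and 4990 of them carried a standard symbol. No coordinates were used. No fission yeast probe sets were used here, although the array design carries them, so an intended centring on those probe sets was not run. FPR1 and the mitochondrially encoded transcripts were not among the tested probe sets.

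Linear models were fitted to the log2 values of all 9 arrays with limma 3.58.1 in R 4.3.3, with 1 mean per group and a spread shared by the 3 groups. Moderated statistics gave the contrasts CR against NR, RM against NR and RM against CR, and a moderated F statistic tested any difference among the 3 groups. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a probe set was called at an adjusted p under 0.05. Differences are given as log2 values with the standard error (SE) of the fit, and each has 3 arrays per group behind it. Group levels are means with the standard deviation (SD) over 3 arrays.

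Gene lists for 45 pathways, complexes, regulons and marker sets were written before the data were examined, as were the designs, the rule for named genes and the alternatives, except where a later choice is stated. Lists with at least 5 measured members were tested, which left 42. Some lists share members, so their calls are not separate results. The general stress response shares HXK1 with glycolysis, SPI1 with cell wall and HSP26 with chaperones, and the TCA cycle shares SDH3 with the respiratory chain. The test was camera, which asks whether a list's members shifted relative to all other genes, with a preset correlation between genes of 0.01. Camera was repeated with the correlation estimated from the data. That version also takes its degrees of freedom from the residuals of the arrays, not from the number of genes. Fry, which tests a list's own direction without reference to other genes, was an alternative. List p-values were adjusted over the 42 lists. Member counts were made over all tested probe sets and again adjusted over the list alone.

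The rule for named genes took, for each contrast with NR, the 10 highest and 10 lowest log2 differences among genes with a standard symbol that were called and whose arrays did not overlap between groups. It added up to 3 members of each called list, those with the largest change in the list's direction that were called and did not overlap. Genes named for a list are thus its extremes. It also added 24 fixed genes of nutrient signalling, glucose metabolism and stress defence. For RM against CR it took 6 highest, 6 lowest and members of called lists chosen in the same way. Some list members and fixed genes are left out of the text. Genes outside the rule are identified as chosen after their values were seen.

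Both contrasts with NR used the same 3 NR arrays, which ties their chance values together. Their overlap was therefore compared with 100 simulated data sets without any effect and with the overlap of independent lists of the observed sizes.

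The fitting functions were tested on simulated data before use. In 20 runs per contrast, 200 of 5498 probe sets were changed by log2 sizes of 0.5, 1, 2 or 4. With each group's own measured spread, the shares recovered for CR against NR were 33.4%, 75.6%, 95.6% and 99.8%. For RM against NR they were 33.6%, 76.1%, 95.9% and 99.7%, and for RM against CR 30.4%, 74.7%, 96.2% and 99.7%. Unchanged probe sets made up 25.9% of calls for CR against NR, 34.6% for RM against NR and 3.80% for RM against CR in this setting. With equal spread in all groups those shares were 5.78%, 5.62% and 5.30%. A list shifted by 0.5 was called by camera in 20 of 20 runs for CR against NR, and 0 lists were called over these runs without a shift. Genes were drawn independently in these runs. They therefore give no error rate for lists of correlated genes, such as ribosomal proteins with an estimated correlation of 0.658.

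Alternatives covered fits on only the groups compared, the replicate number as a block, omission of dim probe sets (mean below the 25th percentile), use of all 5716 probe sets, repeated quantile normalization, median centring, an intensity trend with robust moderation, an unmoderated linear model, array weights, stricter thresholds and omission of each array. A further 3 were added after seeing the data, namely averaging the CR arrays into 1 sample, weights estimated per group, and omission of the 128 probe sets whose names mark shared transcripts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.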

Results

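Gene expression was profiled in cultures of Saccharomyces cerevisiae in the BY4741 background, a laboratory strain in which LEU2, MET17 and URA3 are deleted and HIS3 is deleted in part, at day 5 after inoculation. The design compared full glucose (NR, 2%), calorie restriction by lowered glucose (CR, 0.5%) and rapamycin at full glucose (RM, 100 nM), with 3 arrays per group. The strain's deleted genes were checked first. URA3 read between 0.71 and 1.03 on the log2 scale over the 9 arrays, LEU2 between 1.71 and 2.01 and MET17 between 1.18 and 1.67, where the array medians lay between 6.86 and 6.94. HIS3 read between 5.38 and 6.83 on the same arrays, which checks nothing, because the place of its probes relative to the deleted part was not available.

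The groups differed in how closely their arrays resembled each other. The median SD over probe sets was 0.29 in NR, 0.055 in CR and 0.16 in RM. Correlations across probe sets between arrays of a group ran from 0.929 to 0.977 in NR, from 0.9975 to 0.998 in CR and from 0.980 to 0.995 in RM. The first principal component held 72.6% of the variance and placed the CR arrays apart from the rest, and the second held 15.6% and separated RM from NR. Array NR 3 lay at -51.7 on the first component, beyond NR 1 at -25.2 and NR 2 at -34.7. The median level of cytosolic ribosomal protein genes was 10.1 on NR 3 against 9.59 on NR 1 and 9.62 on NR 2, and that of glycolytic genes was 11.6 against 10.8 and 11.1. Markers of the MATa mating type, that of the strain, had medians of 6.97, 7.37 and 8.69 on NR 1, NR 2 and NR 3, between 6.27 and 6.40 on the CR arrays and between 6.95 and 7.54 on the RM arrays. The 4 MATalpha markers, too few to test, had array medians of 4.77, 4.38 and 6.12 in NR, 4.77 to 5.26 in CR and 4.41 to 4.78 in RM.

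**Figure D1:**
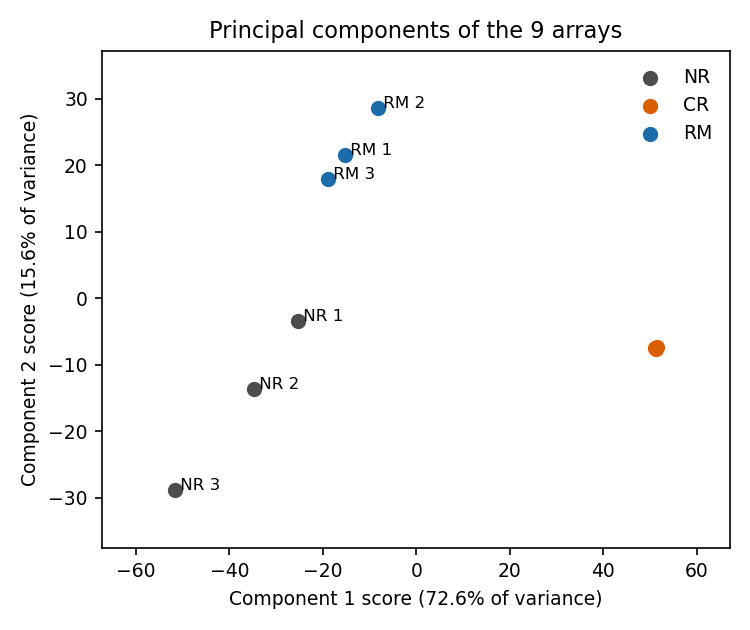
Principal component scores of the 9 arrays from the tested probe sets, 1 point per array, coloured by group, with the share of variance on each axis. The 3 CR points overlap near 51 on the first component, and NR 3 lies at -51.7, farthest from them.

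The comparison of CR with NR addressed what lowered glucose changed in expression at day 5. By camera with the preset correlation, lists of protein synthesis, glycolysis, chaperones and respiration were called lower in CR, and autophagy, peroxisome biogenesis and the iron regulon higher. Camera with an estimated correlation called 0 of these lists (lowest adjusted p = 0.646). Fry, which makes no comparison with other genes and called 31 of the 42 lists, called each of the 17 lists that camera called. Its adjusted p for them ran from 3.23e-06 for ethanol and acetate metabolism to 0.0473 for ergosterol synthesis. The gene with the highest increase was GPX2, a glutathione peroxidase, at 44.0-fold, and the one with the strongest decrease was PDR12, a plasma membrane exporter of weak acids, at 42.8-fold lower. In all, 3791 of 5498 probe sets were called, 1934 higher and 1857 lower in CR, and 2077 of them differed at least 2-fold. The arrays of both groups did not overlap in 75.5% of probe sets, where chance gives 10%.

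Cytosolic ribosomal protein genes fell almost as a block. Of 127 measured, 123 fell and 0 rose in CR, with a median log2 difference of -2.11 (adjusted p = 2.16e-27, camera). This call was lost with an estimated correlation (adjusted p = 0.646 with an estimated correlation). RPS21B went from 10.60 ± 0.31 in NR to 7.01 ± 0.02 in CR (SD, n = 3 arrays each), a difference of -3.60 ± 0.16 (SE), and RPL22A and RPS9A were lower by -3.90 and -3.66. Ribosome biogenesis genes, which act in processing and assembly of ribosomal subunits, showed 98 of 138 lower and 13 higher, with a median of -0.87 (adjusted p = 1.19e-07, camera, and adjusted p = 0.653 with an estimated correlation). Among them RRB1, PWP1 and NSR1 were lower by -3.61, -3.43 and -3.35. On the CR arrays RRB1 read between 2.93 and 3.37 and PWP1 between 2.71 and 3.26, not far above the deleted LEU2, so the size of their differences is uncertain. Of 33 translation factors, 22 fell and 3 rose (adjusted p = 0.00161, camera, and adjusted p = 0.646 with an estimated correlation), with YEF3, the fungal elongation factor 3, lower by -2.31 ± 0.39.

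Glycolytic genes had the lowest median of any list, -3.17, with 14 of 16 lower and 0 higher (adjusted p = 2.67e-06, camera, and adjusted p = 0.646 with an estimated correlation). HXK2, the hexokinase that also takes part in glucose repression, was lower by -4.84 ± 0.37, PGK1 by -4.67 ± 0.54 and TPI1 by -3.75 ± 0.29. Of 14 genes of gluconeogenesis and the glyoxylate cycle, 10 fell and 0 rose (adjusted p = 0.00174, camera, and adjusted p = 0.646 with an estimated correlation), led by malate synthase MLS1 at -4.45 ± 0.25. Of 18 genes of ethanol and acetate metabolism, 9 fell and 2 rose (adjusted p = 0.0481, camera, and adjusted p = 0.646 with an estimated correlation). There the aldehyde dehydrogenase ALD6 was lower by -5.30 ± 0.33 and the pyruvate decarboxylase PDC1 by -3.10 ± 0.17. This last list lost its call in 5 of the 20 alternatives that kept camera and the preset correlation, with a highest adjusted p of 0.0743. These were the fits without NR 1, NR 2 or RM 2 (adjusted p = 0.0599, 0.0743 and 0.0503, camera), with only the groups compared (0.0522) and with median centring (0.0535).

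Respiratory chain and ATP synthase genes fell in 31 of 44 cases and rose in 5, with a median of -0.89 (adjusted p = 4.30e-05, camera, and adjusted p = 0.653 with an estimated correlation). CYT1, cytochrome c1, was lower by -3.62 ± 0.16, and HAP4, the activator subunit of the complex that induces respiratory genes, by -3.03 ± 0.12. Genes of the TCA cycle and pyruvate dehydrogenase showed 9 of 20 lower and 1 higher (adjusted p = 0.00951, camera, and adjusted p = 0.653 with an estimated correlation), with SDH3 lower by -3.12 ± 0.50.

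Chaperone genes were lower in 25 of 26 cases with 0 higher, at a median of -1.78 (adjusted p = 2.09e-09, camera, and adjusted p = 0.646 with an estimated correlation). HSP30, HSP82 and SSE1 were lower by -4.60, -3.63 and -3.56. The general stress response, genes under the activators Msn2 and Msn4, fell in 30 of 46 cases and rose in 3, at a median of -0.91 (adjusted p = 2.80e-05, camera, and adjusted p = 0.646 with an estimated correlation). GPP2, SPI1 and HXK1 were lower by -4.21, -3.39 and -3.18, and catalase CTT1 by -1.78. MSN2 itself was higher, by 1.63 ± 0.12. Of 27 cell wall genes, 14 fell and 3 rose (adjusted p = 0.00951, camera, and adjusted p = 0.653 with an estimated correlation), with PIR3 lower by -4.38 ± 0.17.

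Of the biosynthetic lists, 3 were called lower, while fatty acid synthesis (2 of 9 higher and 2 lower, adjusted p = 0.993) and sulfur amino acid metabolism (6 of 23 higher and 9 lower, adjusted p = 0.596) were not called. Amino acid biosynthesis fell in 28 of 52 genes and rose in 7 (adjusted p = 0.00577, camera, and adjusted p = 0.771 with an estimated correlation), with ILV5 lower by -3.06 ± 0.15. Purine biosynthesis fell in 10 of 16 genes and rose in 1 (adjusted p = 0.0229, camera, and adjusted p = 0.771 with an estimated correlation), with ADE12 lower by -2.34 ± 0.33. Ergosterol synthesis fell in 14 of 26 genes and rose in 2 (adjusted p = 0.0229, camera, and adjusted p = 0.777 with an estimated correlation), with ERG11 lower by -2.89 ± 0.56. The ergosterol call did not hold without NR 3 (adjusted p = 0.0861, the highest over the alternatives that kept camera and the preset correlation).

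Autophagy genes rose in 25 of 34 cases and fell in 4, at a median of 1.01 (adjusted p = 3.32e-04, camera, and adjusted p = 0.653 with an estimated correlation). ATG20, ATG15 and ATG9 were higher by 2.14 ± 0.17, 1.95 ± 0.16 and 1.89 ± 0.16. Peroxisome biogenesis genes rose in 18 of 25 cases and fell in 2, at a median of 0.91 (adjusted p = 0.00208, camera, and adjusted p = 0.653 with an estimated correlation), with PEX13 higher by 2.44 ± 0.22. The iron regulon, genes of iron uptake and use under Aft1 and Aft2, rose in 15 of 25 cases and fell in 4, at a median of 0.99 (adjusted p = 0.0426, camera, and adjusted p = 0.646 with an estimated correlation). ISU2, a scaffold for iron-sulfur cluster assembly, was higher by 3.43 ± 0.18 and the mitochondrial iron carrier MRS4 by 2.30 ± 0.22. The iron regulon lost its call in 3 of the 20 alternatives that kept camera and the preset correlation, with a highest adjusted p of 0.113. Adjusted over the list alone, the member counts of these 17 lists were the same, except for 99 lower in ribosome biogenesis, 26 higher in autophagy and 2 higher in cell wall.

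GPX2 went from 5.15 ± 0.05 in NR to 10.61 ± 0.18 in CR (SD, n = 3 arrays each), a difference of 5.46 ± 0.12 (SE). It was followed by SRX1, a sulfiredoxin that restores peroxiredoxins, at 3.99 ± 0.28, SRL4 at 3.74 ± 0.94, OSW7 at 3.54 ± 0.12 and ISU2. SRL4 read 7.89, 5.92 and 2.99 on NR 1, NR 2 and NR 3 and between 9.29 and 9.37 in CR. The next were the transcription factor TOG1 at 3.21, ALG7 of N-glycosylation at 3.20, MND2 of the anaphase-promoting complex at 3.04, the thioredoxin reductase TRR1 at 2.98 and TBS1 at 2.98. ALG7 is the direct neighbour of GPX2 in the gene table. Among the lowest were PDR12 at -5.42 ± 0.29, ALD6, and the first pyrimidine biosynthesis enzyme URA2 at -5.23 ± 0.22. They were followed by the polyamine exporter TPO2 at -4.98 ± 0.38, HXK2, the dihydroorotate dehydrogenase URA1 at -4.76 ± 0.16, PGK1, HSP30, EGO4 at -4.59 ± 0.17 and MLS1. TPO2 read between 3.05 and 3.60 on the CR arrays, close to the levels of RRB1 and PWP1, so the size of its difference is uncertain too.

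Genes of nutrient signalling named before the data were opened did not move together. The kinase genes SCH9 and SNF1 were higher in CR by 1.74 ± 0.12 and 1.22 ± 0.13, and the NAD-dependent deacetylase gene SIR2 by 0.83 ± 0.19. The nicotinamidase PNC1 was lower by -0.56, the mitochondrial superoxide dismutase SOD2 by -1.71, HSP26 by -1.44, CIT2 by -0.88 and GCN4, the activator of amino acid synthesis, by -0.83. TOR1 (0.14 ± 0.19), RIM15 (0.09 ± 0.19), GAP1 (-0.54 ± 0.47), HXT2 (-0.05 ± 0.60), ADH2 (0.54 ± 0.70) and HSP12 (-0.25 ± 0.12) were not called. Without NR 1, GAP1 was called at -1.10, and without NR 3, HXT2 and HSP12 were called at -0.87 and -0.31. MEP2, an ammonium permease, was not called at -0.01 ± 0.58. It read 10.8 on NR 3 against 8.28 and 8.25 on the other NR arrays, and without NR 3 the difference was 0.85 and called. The glucose transporter HXT1 (-1.03 ± 0.34), SUC2 (-0.54 ± 0.18) and MIG1 (0.71 ± 0.27) were called, and each lost its call in several alternatives that left out 1 array. HXT1 was dim, between 3.22 and 3.70 on the CR arrays and 3.57 on NR 3, so the size of its difference is uncertain. SRL4, SIR2 and PNC1 lost theirs when the CR arrays counted as 1 sample.

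Lists without a call in CR included nitrogen catabolite repressed genes, with 6 of 32 higher and 8 lower (adjusted p = 0.660), fatty acid beta-oxidation, with 6 of 20 higher and 0 lower (adjusted p = 0.491), and mitochondrial ribosome genes, with 24 of 71 higher and 14 lower (adjusted p = 0.625). The proteasome list showed 19 of 34 higher and 6 lower (adjusted p = 0.0542), and MATa markers showed 6 of 7 lower (adjusted p = 0.0550). Over the 20 alternatives that kept camera and the preset correlation, MATa markers were called in 6, namely without NR 1, NR 2 or NR 3, with the replicate block and under both kinds of array weights (adjusted p from 0.0194 to 0.0899, and 0.0373 with the block). The proteasome was called in 2, without NR 2 and with an intensity trend (adjusted p from 0.0289 to 0.219). The labels describe the CR arrays as biological replicates, and their small spread leaves open how separate the cultures were. Counting them as 1 sample lowered the calls from 3791 to 2365. The spread shared by the 3 groups overstates that of CR and understates that of NR, and in simulated data with the same unequal spread and 200 of 5498 probe sets changed a mean of 53.2 unchanged probe sets were called per run. Those simulations held far fewer changed probe sets than were called here, so they give no error rate for these calls.

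**Figure D2:**
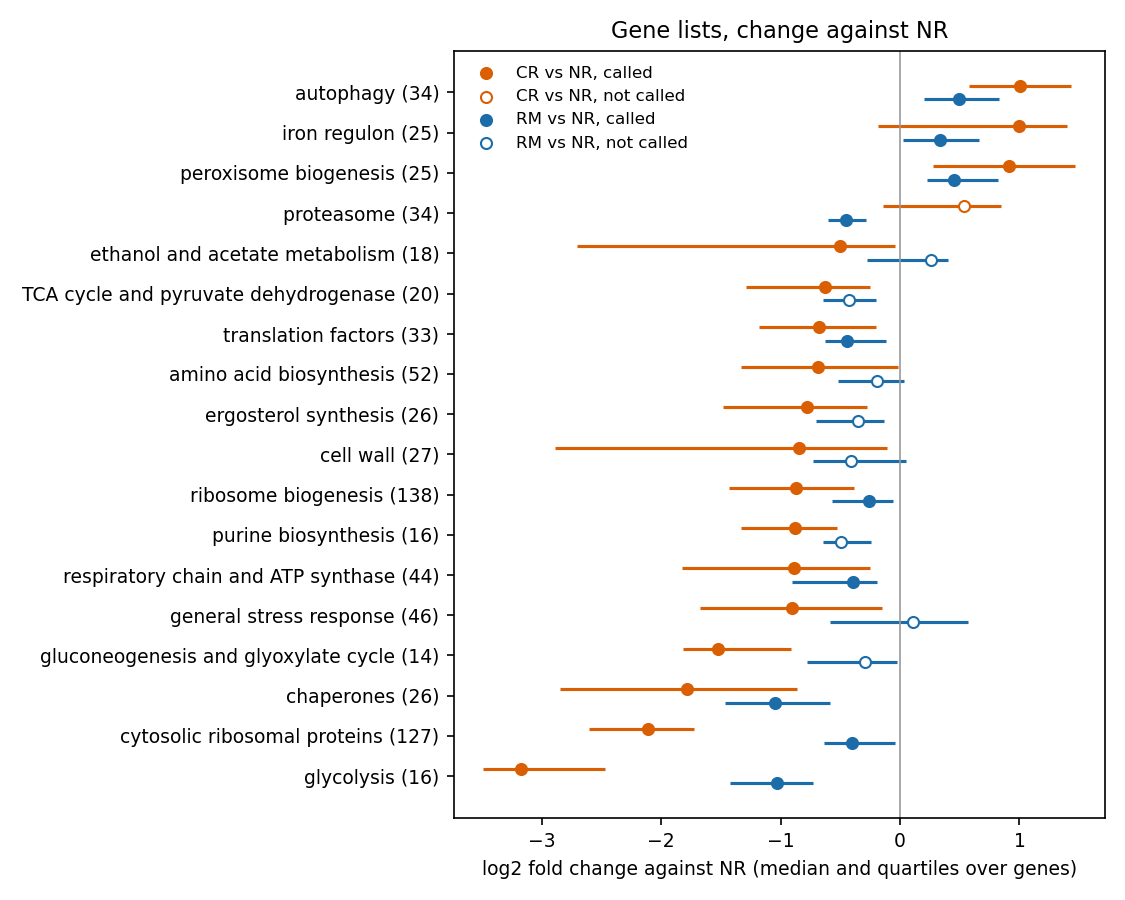
Median log2 difference from NR (points) with quartiles over genes (lines) for gene lists called in CR or RM, with the number of measured genes in brackets and open points for lists not called. Cytosolic ribosomal proteins stand at -2.11 in CR and -0.40 in RM, and glycolysis at -3.17 and -1.03.

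The comparison of RM with NR addressed what rapamycin changed at full glucose. The genes with the highest increases included the zinc-regulated ZPS1, ZRT1 and ZRT2, and those with the strongest decreases included URA1 and URA2 of pyrimidine synthesis. ZPS1, a cell surface protein induced at low zinc, was 24.6-fold higher in RM, and the high-affinity zinc transporter ZRT1 was 14.7-fold higher. URA1 was 12.4-fold lower. In all, 2031 of 5498 probe sets were called, 967 higher and 1064 lower, and 468 of them differed at least 2-fold. The balance of higher and lower calls depended on the setting. It turned with repeated quantile normalization (1016 higher and 952 lower), median centring (1010 and 996) and omission of dim probe sets (862 and 755). The arrays of both groups did not overlap in 43.4% of probe sets, where chance gives 10%.

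Chaperone genes fell in 22 of 26 cases and rose in 1, at a median of -1.04 (adjusted p = 2.55e-09, camera, and adjusted p = 0.856 with an estimated correlation). BTN2 was lower by -2.09 ± 0.20, and the Hsp70 genes SSA4 and SSA1 by -1.93 ± 0.14 and -1.75 ± 0.36. Proteasome genes fell in 21 of 34 cases and rose in 1, at a median of -0.46 (adjusted p = 3.42e-06, camera, and adjusted p = 0.856 with an estimated correlation), with PRE7 lower by -1.24 ± 0.14. Adjusted over the list alone, 23 proteasome genes fell.

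Glycolytic genes fell in 12 of 16 cases and rose in 1, or fell in 13 adjusted over the list alone, at a median of -1.03 (adjusted p = 3.67e-04, camera, and adjusted p = 0.894 with an estimated correlation). HXK2 was lower by -2.98 ± 0.37 and TPI1 by -1.67 ± 0.29. Respiratory chain and ATP synthase genes fell in 21 of 44 cases and rose in 3, or fell in 25 adjusted over the list alone (adjusted p = 6.14e-04, camera, and adjusted p = 0.933 with an estimated correlation). ATP2 and ATP5 were lower by -1.70 ± 0.22 and -1.33 ± 0.26, and HAP4 by -0.94 ± 0.12.

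The lists of protein synthesis genes were called lower in RM by camera, and these calls depended on the method. Fry did not call ribosomal proteins or ribosome biogenesis (adjusted p = 0.321 and 0.132, fry). It called translation factors (adjusted p = 0.0101, fry) and the other lists that camera called in this contrast. With array weights camera called none of the 3 lists (adjusted p = 0.0736, 0.887 and 0.161 for ribosomal proteins, ribosome biogenesis and translation factors). Those weights rested almost wholly on NR 2 (4.44) and RM 1 (16.9), against 0.0654 to 0.429 for the other NR and RM arrays. That setting thus compares little more than 1 array with 1. Of 127 cytosolic ribosomal protein genes, 37 fell and 6 rose, or 31 and 6 adjusted over the list alone, at a median of -0.40 (adjusted p = 9.66e-04, camera, and adjusted p = 0.933 with an estimated correlation). RPP2B and RPL13A were lower by -1.48 ± 0.33 and -1.33 ± 0.29. Of 138 ribosome biogenesis genes, 31 fell and 5 rose, or 27 and 3 adjusted over the list alone (adjusted p = 0.00283, camera, and adjusted p = 0.933 with an estimated correlation), with GAR1 lower by -1.44 ± 0.34. Of 33 translation factors, 17 fell and 2 rose, the same numbers adjusted over the list alone (adjusted p = 0.00285, camera, and adjusted p = 0.856 with an estimated correlation), with TIF34 lower by -0.85 ± 0.16. Without NR 3, whose ribosomal protein median was the highest of the NR arrays, the median of the ribosomal protein list was -0.19 and the list was not called (adjusted p = 0.200, the highest over the alternatives that kept camera and the preset correlation). Ribosome biogenesis, with a median of -0.26, kept a similar median without NR 3 (-0.24) or NR 1 (-0.27) but was not called (adjusted p = 0.0578 and 0.0640, with a highest of 0.887 over those alternatives, under array weights).

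Autophagy genes rose in 17 of 34 cases and fell in 4, or rose in 20 adjusted over the list alone, at a median of 0.49 (adjusted p = 3.13e-04, camera, and adjusted p = 0.894 with an estimated correlation). ATG36, the receptor for peroxisome turnover, was higher by 2.13 ± 0.15, ATG41 by 1.59 ± 0.17 and ATG8 by 0.73 ± 0.17. Peroxisome biogenesis genes rose in 10 of 25 cases with 0 lower (adjusted p = 4.53e-04, camera, and adjusted p = 0.856 with an estimated correlation), with PEX3 higher by 1.43 ± 0.26. The iron regulon rose in 8 of 25 cases and fell in 1 (adjusted p = 0.0217, camera, and adjusted p = 0.856 with an estimated correlation), with the siderophore transporters ENB1 and SIT1 higher by 1.28 ± 0.19 and 1.23 ± 0.11. The iron regulon was not called without NR 3 (adjusted p = 0.0964, the highest over the alternatives that kept camera and the preset correlation). Adjusted over the list alone, the chaperone, peroxisome and iron counts were the same.

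ZPS1 went from 5.83 ± 0.48 in NR to 10.45 ± 0.24 in RM (SD, n = 3 arrays each), a difference of 4.62 ± 0.23 (SE). ZRT1 followed at 3.88 ± 0.21, and the low-affinity zinc transporter ZRT2 at 2.95 ± 0.19. Genes of sporulation and meiosis also stood among the highest, namely the dityrosine transporter DTR1, MSH4 at 2.52 ± 0.27 and SPS4 at 2.26 ± 0.40. DTR1 read 2.20 on each NR array, near the level of the deleted LEU2, and 5.38 ± 0.24 in RM (SD, n = 3 arrays), so its difference has no reliable size. The list of meiosis and sporulation genes was not called, with 8 of 37 higher and 4 lower (adjusted p = 0.557). The remaining highest genes were the RNA-binding protein PHO92, from 5.51 in NR to 8.51 in RM, the transcription factor CIN5 at 2.72, the daughter cell glucanase DSE4 at 2.39 and the glutathione transferase GTO1 at 2.33. The lowest were URA1 at -3.63 ± 0.16, the mitochondrial metal transporter MMT1 at -3.39 ± 0.23, HXK2, URA2 at -2.35 ± 0.22, TPO2 at -2.24 ± 0.38 and the dolichol kinase SEC59 at -2.21 ± 0.18. BTN2, PDR12 at -2.06 ± 0.29, PGK1 at -2.03 ± 0.54 and ZPR1 at -1.99 ± 0.13 completed this set. PGK1 lost its call without RM 1, RM 2 or NR 2.

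Among the genes named before the data were opened, CTT1 rose by 1.23 ± 0.19 in RM, and MIG1, the glucose repressor, by 1.41 ± 0.27. HSP26 fell by 0.48, and the general stress response as a list was not called, with 13 of 46 higher and 15 lower (adjusted p = 0.828). MSN2 was higher by 0.47 ± 0.12, a call lost without RM 1, as were those of SOD2 (-0.70 ± 0.18, lost without RM 2 too) and PNC1 (-0.38 ± 0.11, lost in most omissions of 1 array). The calls of MSN2, SOD2, PNC1, HSP26, ATG8 and PGK1 in RM were also lost when only NR and RM entered the fit. TOR1 (-0.13 ± 0.19), GAP1 (-0.26 ± 0.47), MEP2 (-1.38 ± 0.58), GCN4 (-0.37 ± 0.13), SCH9 (0.13 ± 0.12), SNF1 (0.18 ± 0.13), SIR2 (0.21 ± 0.19), HSP12 (0.01 ± 0.12) and CIT2 (-0.12 ± 0.11) were not called. Without NR 1, TOR1, MEP2 and GCN4 were called at -0.36, -1.80 and -0.43, and without NR 3, MEP2 was called at -0.52. Nitrogen catabolite repressed genes, a class known to respond to TORC1 inhibition, were higher in 3 of 32 cases and lower in 4 (adjusted p = 0.836). The count of calls depended on whether CR was in the fit and on single arrays, with 892 calls when only NR and RM entered, 1164 without RM 1 and 1327 without RM 2. The SEs given for this contrast rest on a spread that includes the CR arrays, and they are too small for genes that varied less in CR than in NR and RM. In simulated data with the measured unequal spread and 200 of 5498 probe sets changed, a mean of 80.8 unchanged probe sets were called per run, which gives no error rate for a contrast with 2031 calls.

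**Figure D3:**
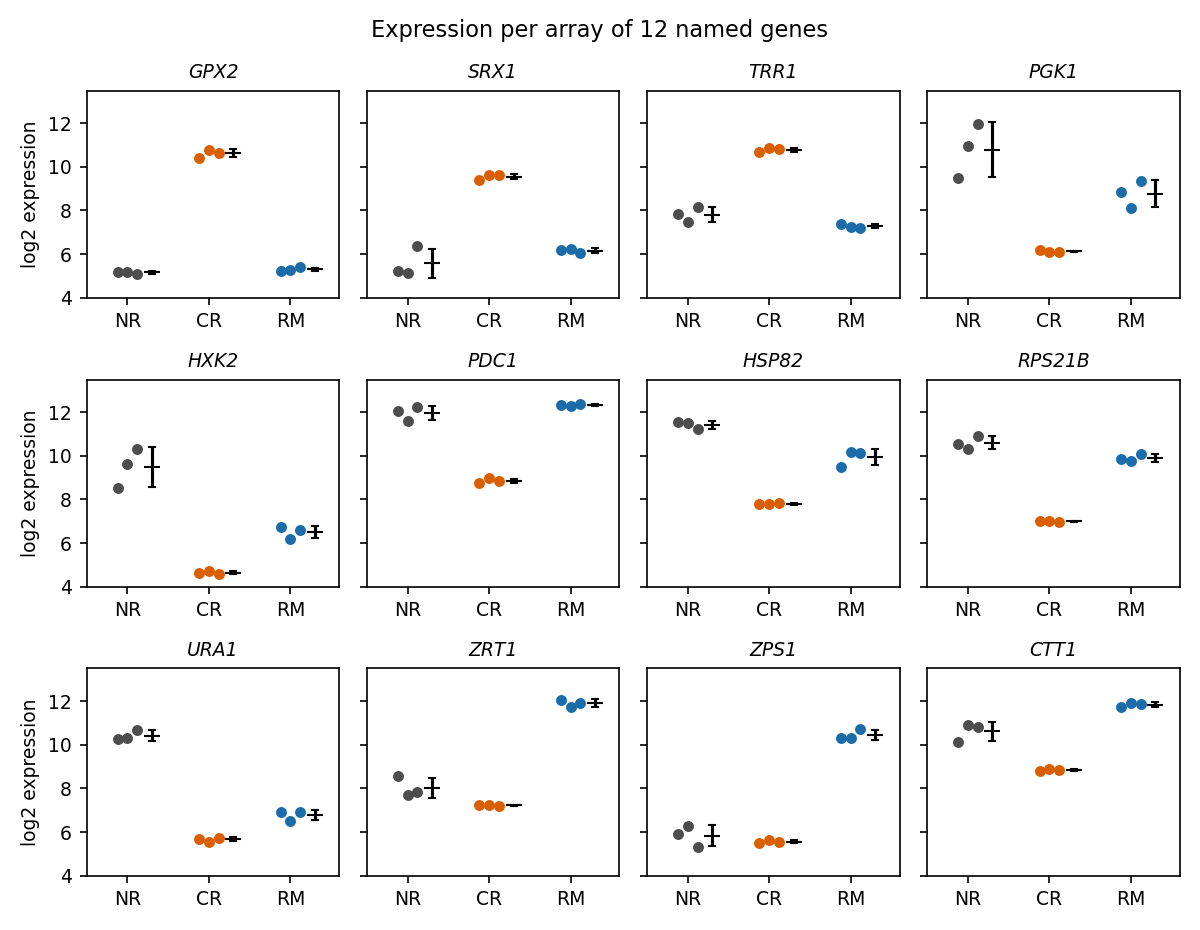
Log2 expression of 12 named genes on each array (points, in the order of replicate number), with the group mean and SD beside them (black). GPX2 stands at 10.61 in CR against 5.15 in NR and 5.29 in RM, and ZRT1 at 11.91 in RM against 8.03 in NR and 7.23 in CR.

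RM and CR were compared directly, as a test of where both treatments differed. ZPS1 and ZRT1 were higher in RM, and GPX2, TRR1 and SRX1 were lower. By camera with the preset correlation, ribosomal protein and glycolytic genes were called higher in RM and proteasome genes lower, and with an estimated correlation none of these 3 lists was called (adjusted p = 0.691 for each). Antioxidant defence as a list was not called, with 6 of 29 higher and 11 lower (adjusted p = 0.282, camera). In all, 3099 probe sets were called, 1469 higher and 1630 lower in RM, with 1434 differing at least 2-fold. The arrays of both groups did not overlap in 75.9% of probe sets, where chance gives 10%.

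Of 127 cytosolic ribosomal protein genes, 121 were higher in RM than in CR and 0 lower, or 122 adjusted over the list alone, at a median of 1.81 (adjusted p = 1.01e-30, camera, and adjusted p = 0.691 with an estimated correlation). RPL38 was higher by 3.73 ± 0.15. Ribosome biogenesis genes were higher in 70 of 138 cases and lower in 9 (adjusted p = 3.57e-06, camera, and adjusted p = 0.691 with an estimated correlation), with MAK11 higher by 3.91 ± 0.18. Glycolytic genes were higher in 15 of 16 cases and lower in 1 (adjusted p = 8.30e-06, camera, and adjusted p = 0.691 with an estimated correlation), with PGI1 higher by 2.69 ± 0.16. The general stress response was higher in 29 of 46 cases and lower in 1 (adjusted p = 9.77e-08, camera, and adjusted p = 0.691 with an estimated correlation), with RTN2 and CTT1 higher by 3.68 ± 0.26 and 3.01 ± 0.19. Chaperones were higher in 18 of 26 cases and lower in 1 (adjusted p = 2.10e-04, camera, and adjusted p = 0.691 with an estimated correlation), with HSP30 higher by 4.04 ± 0.14.

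Genes of ethanol and acetate metabolism were higher in 10 of 18 cases with 0 lower (adjusted p = 0.00753, camera, and adjusted p = 0.573 with an estimated correlation), with PDC1 higher by 3.46 ± 0.17. Those of gluconeogenesis and the glyoxylate cycle were higher in 9 of 14 cases with 0 lower (adjusted p = 0.00267, camera, and adjusted p = 0.691 with an estimated correlation). Respiratory chain genes were higher in 19 of 44 cases and lower in 2 (adjusted p = 0.0109, camera, and adjusted p = 0.691 with an estimated correlation), with CYT1 higher by 3.39 ± 0.16. Amino acid biosynthesis, with 18 of 52 higher and 8 lower, and cell wall genes, with 11 of 27 higher and 3 lower, were both called at an adjusted p of 0.0381 by camera (adjusted p = 0.691 with an estimated correlation for each). Amino acid biosynthesis was the only called list of this contrast that fry did not call (adjusted p = 0.0577, fry). It was not called without RM 1 either (adjusted p = 0.0571, camera). Cell wall genes were not called without NR 1 or RM 2 (adjusted p = 0.0518 and 0.0541, camera). These camera values were near or at the highest over the alternatives that kept camera and the preset correlation.

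Proteasome genes were lower in RM in 27 of 34 cases and higher in 1, or lower in 28 adjusted over the list alone, at a median of -0.87 (adjusted p = 1.12e-06, camera, and adjusted p = 0.691 with an estimated correlation), with RPN11 lower by -1.60 ± 0.12. Autophagy genes were lower in 17 of 34 cases and higher in 4 (adjusted p = 0.0438, camera, and adjusted p = 0.691 with an estimated correlation), with ATG1 lower by -1.68 ± 0.22. The autophagy call was lost in 8 of the 20 alternatives that kept camera and the preset correlation, among them those without RM 1, RM 3 or NR 2 (adjusted p = 0.0705, 0.0572 and 0.0516, with a highest of 0.102 over the 20, when dim probe sets were left out). Adjusted over the list alone, ribosome biogenesis was higher in 71 cases, and the counts of the other called lists not given above were the same.

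The genes with the highest RM level relative to CR were ZPS1 at 4.88 ± 0.23, ZRT1 at 4.69 ± 0.21, ALD6 at 4.33 ± 0.33, MLS1 at 4.31 ± 0.25 and the glycerol phosphatase GPP1 at 4.31 ± 0.13. The meiotic gene HOP2 came next, but its level in CR, 1.61 ± 0.25, was in the range of the deleted LEU2 and MET17, so its difference from 5.84 ± 0.33 in RM (SD, n = 3 arrays each) has no reliable size. The lowest were GPX2 at -5.32 ± 0.12, TRR1 at -3.51 ± 0.17, SRX1 at -3.39 ± 0.28, the spindle pole body gene CNM67 at -3.29 ± 0.30, and the chromatin remodelling gene SWI1 at -3.12 ± 0.14. ECM23 came next, but it read between 2.48 and 2.85 on the RM arrays, near the level of the deleted LEU2, so its difference has no reliable size. Counting the CR arrays as 1 sample lowered the calls for this contrast. With array weights, which within RM rested almost wholly on RM 1, the calls rose from 3099 to 4863.

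Calls shared by the contrasts of CR and RM with NR were counted next. Both contrasts called 661 probe sets higher and 767 lower, 1428 in the same direction, and 182 in opposite directions. Among genes lower in both were HXK2, URA1, URA2, PDR12, TPO2 and PGK1, and among those higher in both were PEX13 and ATG8. CTT1 was lower in CR and higher in RM. Of the 1428, the change was larger in CR for 1129, and the direct contrast of RM with CR called 748 of them, 698 with the larger change in CR. Independent lists of these sizes would share 340 higher and 359 lower probe sets and 701 in opposite directions. Simulated data without an effect gave a mean of 7.18 shared calls in the same direction, with 27 at most. Few probe sets are called at all in such data, so this count does not measure the overlap expected of lists as long as those observed. The correlation of the log2 differences across probe sets, which are not independent replicates, was 0.591 against 0.855 in simulated data without an effect. Their covariance was 0.437 against 0.0615, a difference of 0.376. With 3 NR arrays the controls could not be split into parts of at least 2 arrays, so part of the excess of shared calls over independent lists may come from the shared controls. The shared count was 660 when each contrast was fitted on its own groups, 838 without RM 1 and 928 without RM 2.

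**Figure D4:**
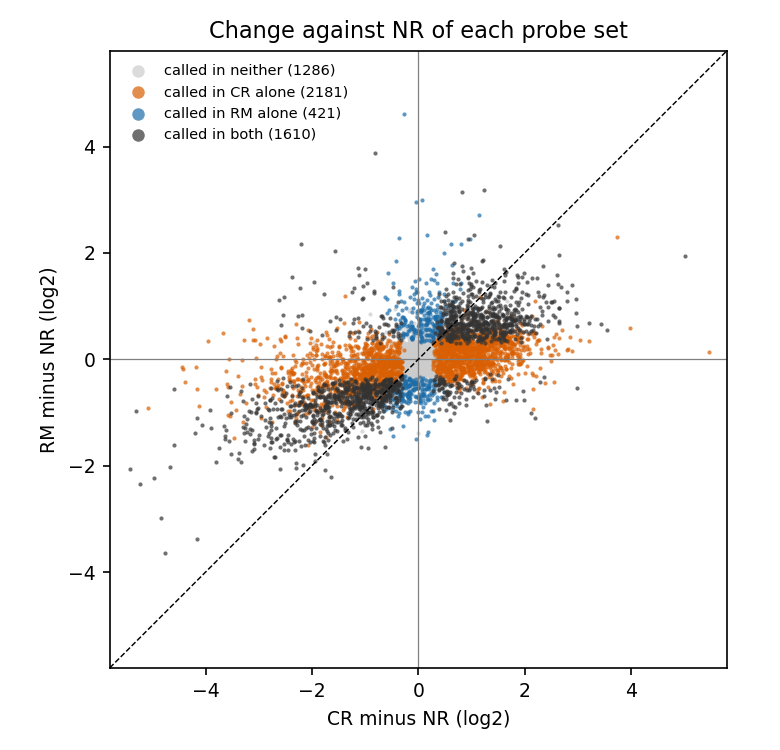
Log2 difference of each tested probe set from NR in CR (horizontal) and in RM (vertical), coloured by the contrasts in which it was called, with the line of equal change dashed. Both contrasts called 1428 probe sets in the same direction and 182 in opposite directions.

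Over all 3 groups, the moderated F statistic called 4146 of 5498 probe sets. The authors' deposited table gave fold changes that matched the group means of the log2 values within 0.001 for 5716 of 5716 probe sets, and p-values that matched Tukey's honest significant difference within 1% for 5716 of 5716. In the authors' deposited table the p-value was under 0.05 for 3548 probe sets between CR and NR, 1917 between RM and NR and 2888 between CR and RM. After Benjamini-Hochberg adjustment of the authors' deposited table these numbers were 3237, 904 and 2474.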

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

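The alternatives that averaged the CR arrays into 1 sample, weighted arrays by group or left out shared probe sets were chosen after seeing the data. Over all alternatives, 166 of 201 pairs of named gene and contrast kept call and direction, and 29 of 39 called lists were called in each alternative that kept camera and the preset correlation. Leaving out 1 array gave 3344 to 4020 calls for CR against NR, 2617 to 3668 for RM against CR, 3668 to 4418 over 3 groups, and 1164 to 2647 for RM against NR. Shared calls then ranged from 838 to 1986, with 1164 and 838 without RM 1, and 1327 and 928 without RM 2. Lists called ranged from 16 to 18, 7 to 12 and 10 to 14 for CR against NR, RM against NR and RM against CR. With only the 2 groups compared, RM against NR gave 892 calls and shared calls were 660. Leaving CR out removes both its low spread and its degrees of freedom, which were not separated. Counting CR as 1 sample gave 2365, 892, 1533 and 2574 calls for the 3 contrasts and the 3 groups, with 528 shared, and 1 CR sample likewise adds nothing to the spread. Weights by group gave 994 calls for RM against NR and 720 shared. A minimum absolute log2 difference of 1 left 2077, 468, 1434 and 2420 calls, and an adjusted p under 0.01 left 840 for RM against NR, both being stricter by construction. Camera with an estimated correlation called 0, 0 and 0 lists, with 2, 1 and 1 at an unadjusted p under 0.05, and fry called 31, 11 and 28. The estimated correlation was 0.658 for ribosomal proteins and 0.558 for glycolysis, far above the preset 0.01. The preset camera p-values of these lists therefore rest on a correlation lower than the estimate. For ethanol and acetate metabolism, which lost its calls too, the estimate was -0.0495. A correlation above the preset thus does not account for that loss. Its unadjusted p for CR against NR was 0.0195 by camera with the preset and 0.0449 by camera with the estimate. With an estimate, camera also rests on the residual degrees of freedom of the arrays, not on the number of genes. The lost calls therefore cannot be laid to the correlation alone.

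Array weights, whose estimation stopped before convergence, gave RM 1 a weight of 16.9 against 0.199 and 0.429 for RM 2 and RM 3. NR 2 had 4.44 against 0.118 and 0.0654 for NR 1 and NR 3, so 1 array stood for nearly all of NR and of RM. These weights gave 4355 calls for RM against NR, 4863 for RM against CR, 3041 shared calls and 6 lists for RM against NR. Ribosome biogenesis in RM against NR then shifted in the opposite direction by camera at a median of -0.0106. MEP2 (0.84) and ADH2 (-0.92) in CR against NR, and ADH2 (-1.11) and HSP12 (-0.17) in RM against NR, also turned sign. These gene signs follow from the weight of NR 2, on which MEP2 read 8.25, ADH2 12.70 and HSP12 13.01, with 10.83, 9.21 and 12.68 on NR 3. MEP2 in CR against NR ranged from -0.44 to 0.85 when 1 array was left out. The value of 0.85 came without NR 3 and its reading of 10.83. Why NR 3 differed was not tested here. Leaving out dim probe sets moved the median log2 difference of CR against NR from 0.02 to 0.14. Median centring turned the balance of calls to 1869 higher and 1956 lower for CR against NR, and to 1583 and 1515 for RM against CR. With the replicate number as a block, calls were 3764, 1902, 3042 and 4076, shared calls 1356 and lists 18, 10 and 13, and the block moved no count by over 1.5 times. Residuals of the 9 pairs with the same replicate number correlated from -0.201 to 0.361, with 1 over 0.1, that of NR 3 with RM 3. Not every array correlated best with its own number. Residuals of 3 arrays around their own mean are tied together. These values therefore cannot decide whether arrays of the same number shared more than that number. Centring on fission yeast probe sets was not run, a treatment of probe sets for several genes had none to act on, and the unmoderated model gives no list test. Signal near background limits what can be said of dim genes such as DTR1 and HOP2.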

Other observations

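The lists of Yap1 targets, Zap1 targets and pyrimidine genes, their tests, and the test for a mislabelled array were chosen after the results were seen. Genes of pyrimidine synthesis and uptake fell in CR in 11 of 11 cases, at a median log2 difference of -1.38. Besides URA1 and URA2, the CTP synthase URA7 (-3.03) and the uridine permease FUI1 (-2.77) were lower. Without URA1 and URA2 the median was -1.19, at percentile 0.88 of 10000 random lists matched on mean level. In RM 4 of the 11 fell and 1 rose, with FUI1 at -1.56 and URA4 at -1.24, and without URA1 and URA2 2 of 9 fell and 1 rose, at a median of -0.61 and percentile 1.24. The strain lacks URA3, a step of the same pathway. FUI1, URA4 and URA7 were chosen after their values were seen.

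Further lists had no call in CR. The phosphate regulon had 8 of 15 genes higher and 2 lower (adjusted p = 0.0598, camera), the pentose phosphate pathway 1 of 11 higher and 7 lower (adjusted p = 0.0599), nutrient signalling 16 of 31 higher and 7 lower (adjusted p = 0.176), and antioxidant defence 11 of 29 higher and 8 lower (adjusted p = 0.370). In RM, endoplasmic reticulum folding had 1 of 12 higher and 6 lower (adjusted p = 0.0968) and RNA polymerase I and III 1 of 36 higher and 11 lower (adjusted p = 0.0840). The TCA cycle and pyruvate dehydrogenase in RM had 2 of 20 higher and 5 lower (adjusted p = 0.0907) and ergosterol synthesis 1 of 26 higher and 3 lower (adjusted p = 0.0840). Over the 20 alternatives that kept camera and the preset correlation, the phosphate regulon was called in 1 (lowest adjusted p = 0.0488, highest 0.232), the pentose phosphate pathway in 3 (0.0404 and 0.0899), endoplasmic reticulum folding in 1 (0.0453 and 0.522) and RNA polymerase I and III in 2 (0.0427 and 0.518). In RM, the TCA cycle list was called in 4 (0.0225 and 0.177) and ergosterol synthesis in 4 (0.00216 and 0.707). Leaving out 1 array gave these calls for the pentose phosphate pathway (NR 1), endoplasmic reticulum folding (NR 2), RNA polymerase I and III (RM 1 or NR 2), the TCA cycle (NR 1) and ergosterol synthesis (NR 1 or RM 3). ADH2 read 9.21 on NR 3 against 11.57 and 12.70 on NR 1 and NR 2.

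For each contrast the 6 arrays compared were split anew, with the third group kept in the fit. For CR against NR, RM against NR and RM against CR, the real split gave 3791, 2031 and 3099 calls, and the highest of the other splits gave 0, 0 and 0. In each contrast 1 of 10 splits gave as many as the real one, and 10 splits are too few for a share under 0.05. Over 3 groups, 1 of 100 drawn splits of the 9 arrays, from 280 possible, gave as many as the real 4146, and that 1 was the real split itself. So high a count was thus rare among splits, which does not exclude chance for the grouping of NR against RM. The highest of the other 99 gave 3259. The 3 of them that kept the CR arrays together gave 2523 to 3259, and the highest of the rest gave 223, so most of this count follows from the CR arrays standing apart.

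Differences between NR arrays correlated weakly with CR minus RM across genes, at -0.280 for NR 3 minus NR 1, -0.229 for NR 3 minus NR 2 and -0.154 for NR 2 minus NR 1. After a smooth trend on mean level was removed from both, the first was -0.265 (95% bootstrap interval over genes -0.292 to -0.237). This argues against a scaling that depends on level as the whole cause. NR 3 correlated with the other NR arrays by 0.0449 more than with RM or CR (95% bootstrap interval over genes 0.0406 to 0.0493). The higher correlation argues against a CR or RM array under an NR label. Both intervals resample genes, which are not independent, and hold no variation between cultures. No biological explanation was tested, and a difference in growth stage between the NR cultures may account for the pattern.

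GPX2, SRX1 and TRR1, known targets of the oxidative stress activator Yap1, stood among the highest genes in CR. Of 18 Yap1 targets, 11 rose and 1 fell. Without those 3, 8 rose and 1 fell of 15, and their median of 0.43 lay at percentile 86.3 of 10000 random lists matched on mean level. OYE2, also a listed target, was lower by -3.79, and it and FLR1 were chosen after their values were seen. Against NR, a shift shared by genes of their level may account for the rest of the list. In RM against CR, without those 3, 2 rose and 7 fell, and their median of -0.54 lay at percentile 1.54 of random list medians, with 6 of the 15 not called and FLR1 and OYE2 higher at 1.30 and 1.85. Whether Yap1 activity differed was not tested and stays open.

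ZPS1, ZRT1 and ZRT2, targets of the zinc-responsive activator Zap1, stood among the 5 highest named genes in RM. Of 15 Zap1 targets, 9 rose and 0 fell in RM against NR. Without those 3, 6 of 12 rose at a median of 0.98, at percentile 100 of 10000 random lists matched on mean level, which argues against a shift shared by genes of their level. The list median was 7.71, 7.20 and 8.57 on RM arrays, 6.03, 6.40 and 6.58 on NR arrays and 6.13 to 6.17 on CR arrays, so 3 of 3 RM arrays lay above all others. An effect of rapamycin and a difference of medium or handling that goes with the RM cultures, such as available zinc, cannot be told apart, because both coincide with the group.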
